A study of Mus musculus with 7 samples.

How the data were processed

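Small RNA sequencing measured miRNAs in 7 libraries of extracellular vesicles, the membrane particles that cells release, purified from the visceral (epididymal) fat of male mice that lack ApoE and so develop atherosclerosis. Per the labels, the mice were 8 weeks old and received a high-fat diet (HFD) alone or with nicotine at 2 mg/kg/day (HFD+Ni) for 12 weeks. The groups hold 4 HFD and 3 HFD+Ni libraries, all with the batch label 1, and are named here by group and replicate number. The labels do not say whether each library came from 1 animal, so the tests measure the spread between samples, part of which may be technical.

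The deposited table of 820 miRNAs is named as TPM, but its values are RPM: reads scaled to 1000000 miRNA reads per library, written rpm here. Every deposited rpm column sums to 1000000, and its values are whole multiples of a library's smallest step. Dividing by that step returned whole reads for 100% of the values in each library, within a tolerance of 0.1 read, so whole reads were recovered from the deposited rpm. Per the submitters' processing notes the genome was GRCm38 (mm10) and edgeR was used. The aligner, the counter, the miRNA annotation and all versions are not given in the sources used here. The deposited table also gives, for each miRNA, the authors' p-value, FDR and log2 fold change, positive where HFD+Ni is higher. A second deposited list gives the authors' p-value and log2 fold change for 15 miRNAs. Of its 7 columns of deposited rpm values, 6 carry names that match the labels and equal the table of all miRNAs. The other 1 per-sample value column is named as a further HFD+Ni sample, matches no label and was not used; the list has no column for HFD replicate 2.

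Near-identical miRNAs hold near-equal reads in every library. Pairs were sought with at least 200 summed reads and a difference of at most 5% or 2 reads in each library, and pairs with equal reads from 20 summed reads on. This gave 19 pairs with 38 miRNAs, and 9 of the pairs had equal reads in every library. They include miR-10a-5p with miR-10b-5p, miR-29a-3p with miR-29c-3p, miR-103-3p with miR-107-3p, miR-19a-3p with miR-19b-3p and miR-465b-5p with miR-465c-5p. Reads of such pairs cannot be assigned to 1 member, and each value is uncertain. If a read was counted for each miRNA it matches, summed levels and library totals count it more than once. miRNAs that share only part of their reads were not sought.

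The libraries hold between 53626 and 1055902 miRNA reads. In the smallest library 1 read is 18.6 rpm and in the largest 0.947 rpm. A count of 0 allows up to 3 reads, which is 55.9 rpm in HFD+Ni replicate 1 and 2.84 rpm in HFD replicate 2. Where all libraries of a group are at 0, the floor of 3 reads was taken over the pooled reads of the group and folds are given as lower bounds. Poisson intervals are at the 95% level. Intervals and floors cover counting error only, since PCR copies of 1 molecule are not independent.

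Before the data were examined, the comparison, its test, 22 miRNA lists, the rule for named miRNAs and most alternatives were fixed. HFD+Ni was compared with HFD in limma 3.58.1 (R 4.3.3) on log2(rpm + 1), with moderated statistics and a mean-variance trend, over the 387 miRNAs with a mean of at least 5 rpm. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A looser list took miRNAs at unadjusted p under 0.05 and at least 2-fold, without correction for multiple tests. Fold changes on this scale depend on the pseudocount of 1 for miRNAs with few reads, so group means are given beside them. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. The lists were let-7 family, miR-30 family, miR-17-92 and paralog clusters, miRNAs promoting and miRNAs opposing adipocyte differentiation, brown and beige adipocyte, macrophage and inflammatory response, leukocyte, erythrocyte and platelet, endothelial, smooth muscle and mesenchymal, striated muscle, epithelial (miR-200 family), testis and sperm, liver and gut, neuronal, fibrosis and extracellular matrix, hypoxia and angiogenesis, cholesterol and atherosclerosis, nicotine or smoking, the Dlk1-Dio3 imprinted cluster and the Sfmbt2 intron 10 cluster. Library composition and summed lists were compared by exact two-sided permutation over all 35 splits, where the smallest p is 0.0571. Summed lists take all members in the deposited table, also those with a mean under 5 rpm.

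The text names all 15 miRNAs of the deposited list (up to 30 were allowed), the 10 with the smallest p in each direction, the 10 most abundant, and in each list up to 4 abundant members and any at unadjusted p under 0.05. That rule takes 92 miRNAs, of which the ones that carry a comparison are written out and the rest are summarised. Members named outside the rule were chosen after their values were seen. Precursor genes were matched by name in GENCODE release M21 on GRCm38, for 367 of the 387 tested miRNAs.

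The same fit was tested on simulated data with 200 changed miRNAs in each of 20 runs. Reads were drawn from the real means and library sizes, at a dispersion of 0.416 for all miRNAs. For HFD+Ni against HFD, over about 390 miRNAs a run, it recovered 13.1% of 2-fold, 28.2% of 4-fold, 44.3% of 8-fold and 63.9% of 16-fold changes at adjusted p under 0.05. With 200 of about 390 miRNAs changed, the Benjamini-Hochberg threshold is easier to reach than when few change. Recovery of a few changes was not simulated and may be lower. With no change simulated the fit made no call at adjusted p and called 5.28% of miRNAs at unadjusted p under 0.05. camera called an 8-fold change of the Dlk1-Dio3 list in 20 of 20 runs and 0.05 other lists per run. The simulated miRNAs were drawn independently of each other. In the real data the estimated correlation within lists ranged from -0.134 (Sfmbt2 cluster) to 0.906 (striated muscle). The simulated rate of other lists called therefore does not hold for lists of correlated miRNAs.

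Alternatives were pseudocounts of 0.5 and 10, no filter and a filter at 50 rpm, median-of-ratios and quantile scaling, no trend, library weights, a replicate block, each library left out in turn, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Added after seeing the data were thinning of every library to 53626 reads, 1 miRNA per group sharing reads, and leaving out both HFD replicate 2, the deepest library, and HFD+Ni replicate 1, the shallowest. Permutations, intervals and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.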

Results

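Vesicles released by the visceral fat of ApoE-deficient mice on a high-fat diet were profiled for miRNAs with nicotine (HFD+Ni, n = 3) and without it (HFD, n = 4), to ask which vesicle miRNAs differ under nicotine. The HFD libraries held 80817, 1055902, 117459 and 77021 miRNA reads for replicates 1 to 4. The HFD+Ni libraries held 53626, 175892 and 107631 reads for replicates 1 to 3. HFD replicate 2 was therefore far deeper than all others, and it detected 710 miRNAs against 250 to 379 elsewhere. With every library thinned to 53626 reads, 282 ± 21.9 miRNAs (SD, n = 4) were detected in HFD and 297 ± 42.2 (SD, n = 3) in HFD+Ni, a difference within the spread between libraries (exact permutation p = 0.514).

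**Figure D1:**
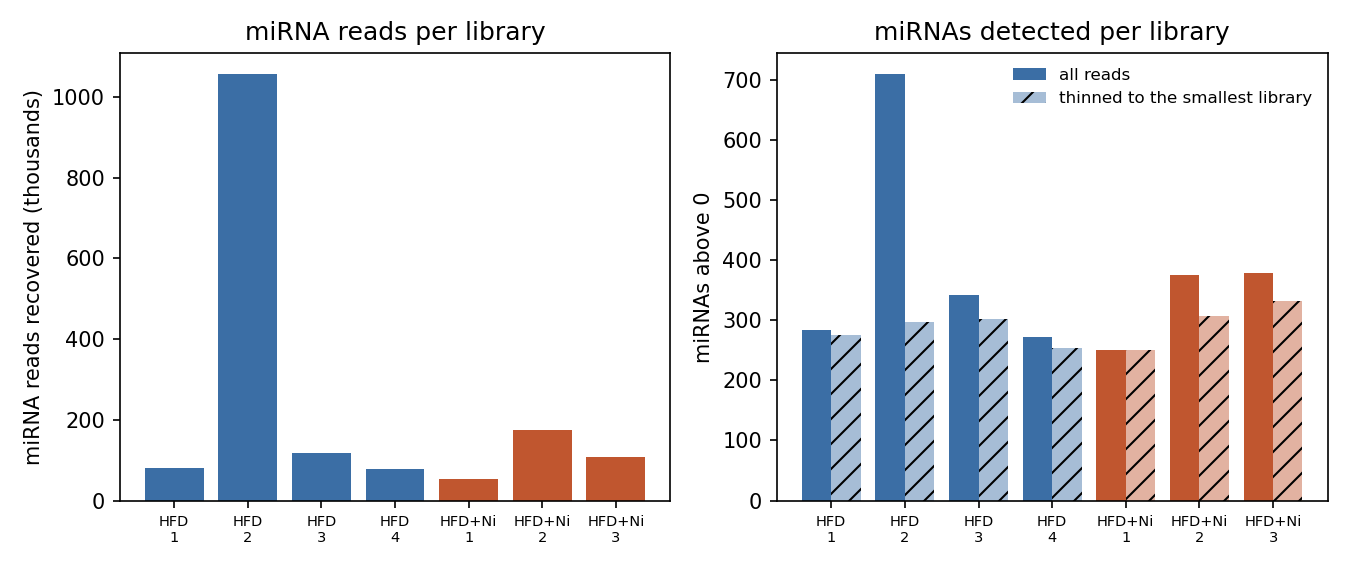
miRNA reads in units of 1000 (left) and miRNAs detected above 0 (right) in each of the 7 libraries, with solid bars for all reads and hatched bars after thinning to the smallest library. HFD replicate 2 stands out with 1055902 reads and 710 miRNAs, and after thinning the libraries range from 250 to 332 miRNAs.

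The vesicle cargo was dominated by the let-7 family, miRNAs that hold back growth programmes in differentiated cells, in both groups. The 9 let-7 members took 53.5% ± 3.68 of the miRNA reads in HFD (SD, n = 4) and 55.5% ± 0.678 in HFD+Ni (SD, n = 3), with 48.0% in HFD replicate 2 and 55.0% to 56.3% in the other libraries (exact permutation p = 0.4). Shares and ranks here may count a read more than once, since reads shared in part among let-7 members were not sought. The most abundant single miRNA was let-7c-5p, with 160172 ± 14833 rpm in HFD and 174061 ± 4073 rpm in HFD+Ni. It is made from Mirlet7c-1 (chromosome 16, 77599657 to 77599750, an intron of Mir99ahg) and Mirlet7c-2 (chromosome 15, 85706603 to 85706697), positions here and below being on GRCm38. let-7a-5p, let-7b-5p, let-7f-5p and let-7e-5p followed with miR-125b-5p, miR-29a-3p and miR-29c-3p, which share reads, miR-143-3p and miR-30a-5p. The 10 most abundant miRNAs together took 67.9% ± 2.02 of reads in HFD and 68.6% ± 0.348 in HFD+Ni (exact permutation p = 0.971). Of the 9 let-7 members 4 lay higher and 5 lower in HFD+Ni, with a median log2 fold change of -0.06 (limma camera adjusted p = 0.919).

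The miRNA with the smallest p in limma, edgeR and DESeq2 was miR-1a-3p, a miRNA of heart and skeletal muscle. It was at 586 ± 443 rpm in HFD (SD, n = 4) and 52.6 ± 19.1 rpm in HFD+Ni (SD, n = 3), 11.1-fold lower, with all HFD+Ni libraries below all HFD libraries (37.3, 73.9 and 46.5 rpm against 223, 1163, 255 and 701 rpm). Its log2 fold change was -3.18 (SE 0.71), which missed the corrected threshold in limma (adjusted p = 0.320) and in edgeR (adjusted p = 0.137) and passed it in DESeq2 (log2 fold change -3.42, adjusted p = 0.00202). The adjusted p from limma ranged from 0.0540 to 0.877 over the alternative settings. The HFD+Ni values rest on 2, 13 and 5 reads. miR-1a-3p comes from Mir1a-1 (chromosome 2, 180389048 to 180389124) and Mir1a-2 (chromosome 18, 10785481 to 10785552, an intron of Mir133a-1hg). miR-133a-3p, made from the same loci, was at 1295 ± 903 rpm in HFD and 654 ± 183 rpm in HFD+Ni, with a log2 fold change of -0.70 (SE 0.57).

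The other 4 miRNAs that lay lower in HFD+Ni at unadjusted p under 0.05 did not pass the corrected threshold in limma (adjusted p = 0.830 for each). miR-223-3p, a myeloid miRNA (chromosome X, 96242817 to 96242926), was at 781 ± 108 rpm in HFD and 385 ± 83.3 rpm in HFD+Ni, 2.03-fold lower, with the groups fully separated. Endothelial miR-126a-5p (chromosome 2, 26591357 to 26591429, within an exon of Egfl7) was at 2532 ± 662 rpm and 1344 ± 647 rpm. miR-21a-5p, which is induced in inflammation and fibrosis (chromosome 11, 86584067 to 86584158, within an exon of Vmp1), was at 11900 ± 3955 rpm and 7637 ± 1008 rpm. miR-137-3p, a neuronal miRNA, was at 25.2 ± 18.1 rpm in HFD and had no read in HFD+Ni, at least 2.83-fold lower against a floor of 8.90 rpm over the group, or 2.18-fold without HFD replicate 3. Over the 7 limma fits with 1 library left out, unadjusted p under 0.05 was kept in 7 for miR-223-3p and 3 for miR-126a-5p. It was kept in 2 for miR-21a-5p and 1 for miR-137-3p.

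The 6 miRNAs that lay higher in HFD+Ni at unadjusted p under 0.05 did not pass the corrected threshold in limma either (adjusted p = 0.830 for each). The close relatives miR-204-5p (chromosome 19, 22750605 to 22750672, an intron of Trpm3) and miR-211-5p (chromosome 7, 64205806 to 64205911, an intron of Trpm1) had means of 266 ± 101 and 179 ± 117 rpm in HFD against 1114 ± 1078 and 580 ± 475 rpm in HFD+Ni. HFD+Ni replicate 1 alone held 2350 rpm of miR-204-5p, and without that library its log2 fold change was 0.92, against 1.68 (SE 0.63) with it. miR-211-5p was at 1119 rpm in the same library, and its log2 fold change was 0.97 without it, against 1.61 (SE 0.72) with it. The 2 relatives are not among the pairs with near-equal reads, but whether they share part of their reads was not tested. miR-34b-5p, of germ cells and multiciliated epithelium (chromosome 9, 51103562 to 51103645), was at 187 ± 54.2 and 438 ± 163 rpm. miR-449a-5p, of the same family and cells, was at 14.3 ± 17.9 and 84.9 ± 43.0 rpm, miR-671-3p at 8.99 ± 12.9 and 77.8 ± 63.3 rpm, and miR-152-5p at 8.99 ± 12.1 and 65.4 ± 42.6 rpm. For these last 3 miRNAs the libraries of both groups held between 0 and 29 reads. With each of the 7 libraries left out in turn, limma kept unadjusted p under 0.05 in 2 cases for miR-449a-5p, 3 for miR-671-3p and 2 for miR-152-5p.

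Across the 387 tested miRNAs, limma called 0 at adjusted p under 0.05 and 11 at unadjusted p under 0.05, where chance alone gives 19.35; 6 of the 11 were higher and 5 lower in HFD+Ni. edgeR called 0 and 28, and DESeq2 called 1 and 19. At unadjusted p under 0.05 and at least 2-fold limma gave 9 miRNAs, 6 higher and 3 lower, a number that was 17 without HFD+Ni replicate 1 and 24 without HFD+Ni replicate 2. With both the deepest library, HFD replicate 2, and the shallowest, HFD+Ni replicate 1, left out, limma called 15 miRNAs at adjusted p under 0.05, all with 0 reads in the HFD libraries used and at most 6 reads in any library. The groups did not overlap for 20 miRNAs, 11 with HFD+Ni above and 9 below, and chance gives 22.1 (5.71%).

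**Figure D2:**
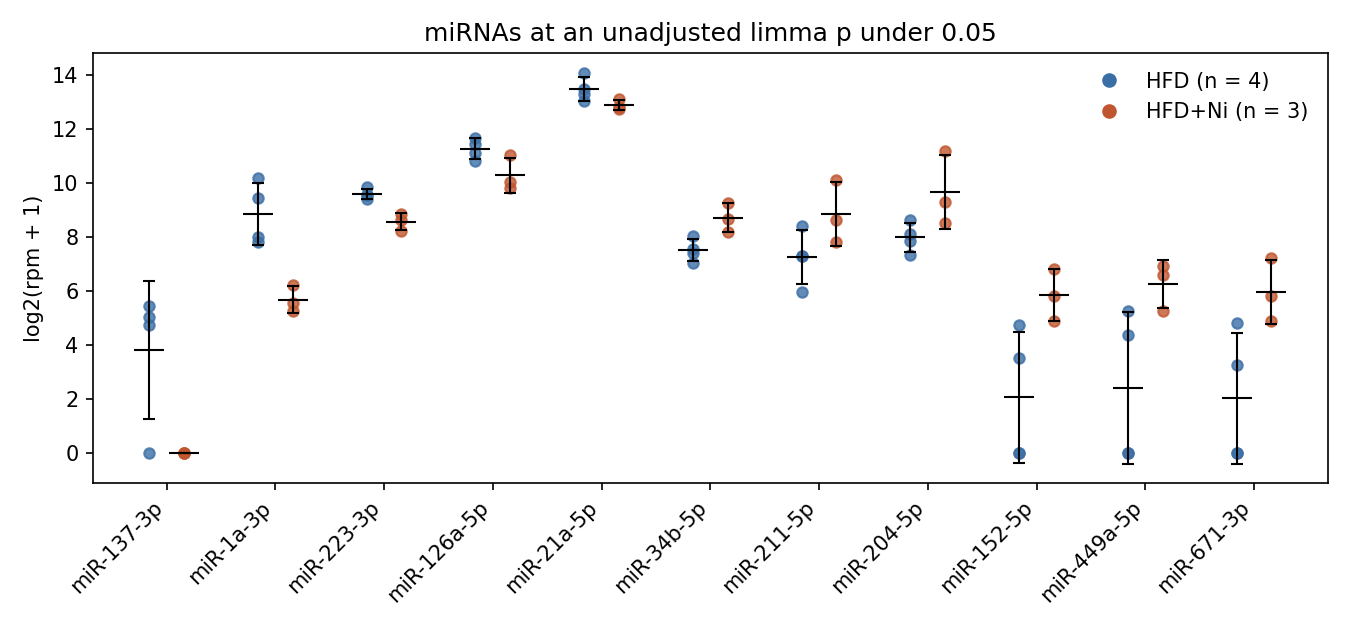
Abundance, as log2(rpm + 1), of the 11 miRNAs at an unadjusted limma p under 0.05, with a point per library (HFD, n = 4; HFD+Ni, n = 3) and black bars for the mean and SD. miR-1a-3p, miR-223-3p, miR-34b-5p, miR-152-5p, miR-449a-5p and miR-671-3p show no overlap between the groups.

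By the lists fixed in advance, miRNAs of muscle, leukocytes, inflammation, atherosclerosis and smoking lay lower in HFD+Ni and those of testis and sperm higher. camera at the preset correlation called 7 of 22 lists, 1 higher and 6 lower, whereas 0 were called with an estimated correlation and 1 by fry. Without HFD replicate 2 and HFD+Ni replicate 1 together, 3 lists were called, all lower. The 6 lower lists overlap: they hold 47 different miRNAs, 39 of them with a log2 fold change below 0, and miR-223-3p, miR-146a-5p and miR-155-5p stand in 4 of the 6.

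Of 14 miRNAs reported elsewhere for nicotine or smoking, 13 lay lower and 1 higher, with a median log2 fold change of -0.65 (camera adjusted p = 0.000558; adjusted p = 0.198 with an estimated correlation). They include miR-21a-5p, miR-223-3p and miR-16-5p, the last at 14792 ± 4743 rpm in HFD and 12518 ± 5766 rpm in HFD+Ni, and the exception was miR-200b-3p. The list was fixed without a direction for its members, so a shared fall does not tell whether they changed as in those reports. Of 16 miRNAs of cholesterol handling and atherosclerosis 13 lay lower, with a median of -0.49 (camera adjusted p = 0.000853; adjusted p = 0.198 with an estimated correlation), among them miR-143-3p of smooth muscle at 29926 ± 16309 and 18362 ± 10105 rpm, and miR-126a-3p at 21834 ± 5907 and 15465 ± 3141 rpm. Both lists were called whichever library was left out.

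Of 8 leukocyte miRNAs 7 lay lower, with a median of -0.60 (camera adjusted p = 0.00790; adjusted p = 0.198 with an estimated correlation). The summed level of all 9 list members in the deposited table was 8291 ± 967 rpm in HFD and 6086 ± 1668 rpm in HFD+Ni. Every HFD+Ni library lay below every HFD library (exact permutation p = 0.0571, the smallest possible, and 0.662 after adjustment over the lists). miR-146a-5p, a brake on inflammatory signalling, was at 2474 ± 983 and 1412 ± 229 rpm, and the lymphocyte miRNA miR-150-5p at 2473 ± 985 and 1852 ± 552 rpm. Of 11 macrophage and inflammatory miRNAs 9 lay lower, with a median of -0.29 (camera adjusted p = 0.0160; adjusted p = 0.198 with an estimated correlation, 0.0146 by fry). Of 9 members of the growth-promoting miR-17-92 and paralog clusters 8 lay lower, with a median of -1.82, or -1.16 with miR-17-5p, unread in HFD+Ni, at its bound (camera adjusted p = 0.0189; adjusted p = 0.198 with an estimated correlation). Most of these members were scarce, and the abundant miR-93-5p was at 2246 ± 574 and 1915 ± 643 rpm. The leukocyte call was lost without HFD+Ni replicate 1 (adjusted p = 0.140), the macrophage call without HFD+Ni replicate 2 (0.0684) or 3 (0.187), and the miR-17-92 call without HFD+Ni replicate 1 (0.140) or 2 (0.0841). A filter at 50 rpm or no filter ended the miR-17-92 call (adjusted p = 0.614 and 0.0858) and the macrophage call (0.0582 and 0.180), and library weights ended the leukocyte call (0.0596).

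All 4 striated muscle miRNAs lay lower, with a median of -1.94 (camera adjusted p = 0.00541; adjusted p = 0.342 with an estimated correlation). miR-1a-3p passed the threshold when adjusted over the list alone (limma adjusted p = 0.00331), and no member of any other list did. miR-133b-3p was at 430 ± 358 rpm in HFD and 282 ± 41.3 rpm in HFD+Ni. miR-206-3p, of skeletal muscle (chromosome 1, 20679010 to 20679082), was read only in HFD replicate 2 at 115 rpm and HFD replicate 4 at 753 rpm, at least 24.4-fold lower in HFD+Ni by group means, a bound that was 4.29-fold without HFD replicate 4. The summed list, here all 6 members in the deposited table, was high in those same libraries, at 4302 and 4025 rpm, against 762 to 1156 rpm in the other 5. The HFD libraries therefore differed among themselves in muscle miRNAs. The call was lost without HFD replicate 4 (adjusted p = 0.128) or HFD+Ni replicate 3 (0.0854).

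Of 14 testis and sperm miRNAs 12 lay higher in HFD+Ni, with a median of 2.31 (camera adjusted p = 0.000488; adjusted p = 0.341 with an estimated correlation). miR-34c-5p, the most abundant, was at 607 ± 183 rpm in HFD and 969 ± 147 rpm in HFD+Ni, with the groups fully separated. Members from the X chromosome, such as miR-741-3p (66796805 to 66796875) and miR-470-5p (66813951 to 66814025), came mainly from HFD+Ni replicates 1 and 3. Counting miRNAs with equal reads once, they summed to 820 and 697 rpm there, to 0 in HFD+Ni replicate 2, and to 0, 28.4, 51.1 and 0 rpm in HFD replicates 1 to 4. The call was lost without HFD+Ni replicate 3 (adjusted p = 0.187) and at a filter of 50 rpm (0.199).

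The epithelial list, the miR-200 family with miR-205-5p, was not called (camera adjusted p = 0.158), although 7 of 8 members lay higher with a median of 0.64. The direction rested on HFD+Ni replicate 1: without that library, or with library weights, camera pointed down (adjusted p = 0.255 and 0.427). The list was called higher without HFD replicate 3 (adjusted p = 0.0462), HFD+Ni replicate 2 (0.0174) or HFD+Ni replicate 3 (0.0394), and with no filter (0.00331). Its summed level was 45165 rpm in HFD+Ni replicate 1 and between 4813 and 13630 rpm in the other 6 libraries. miR-200c-3p (chromosome 6, 124718322 to 124718390) was at 1883 ± 992 rpm in HFD and 4667 ± 5858 rpm in HFD+Ni, and miR-205-5p (chromosome 1, 193507463 to 193507530) at 1494 ± 742 and 4601 ± 6022 rpm. The same library was the least like the others, with correlations across 201 miRNAs of 0.681 to 0.753 against 0.813 to 0.939 for pairs without it; miRNAs are not independent replicates.

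**Figure D3:**
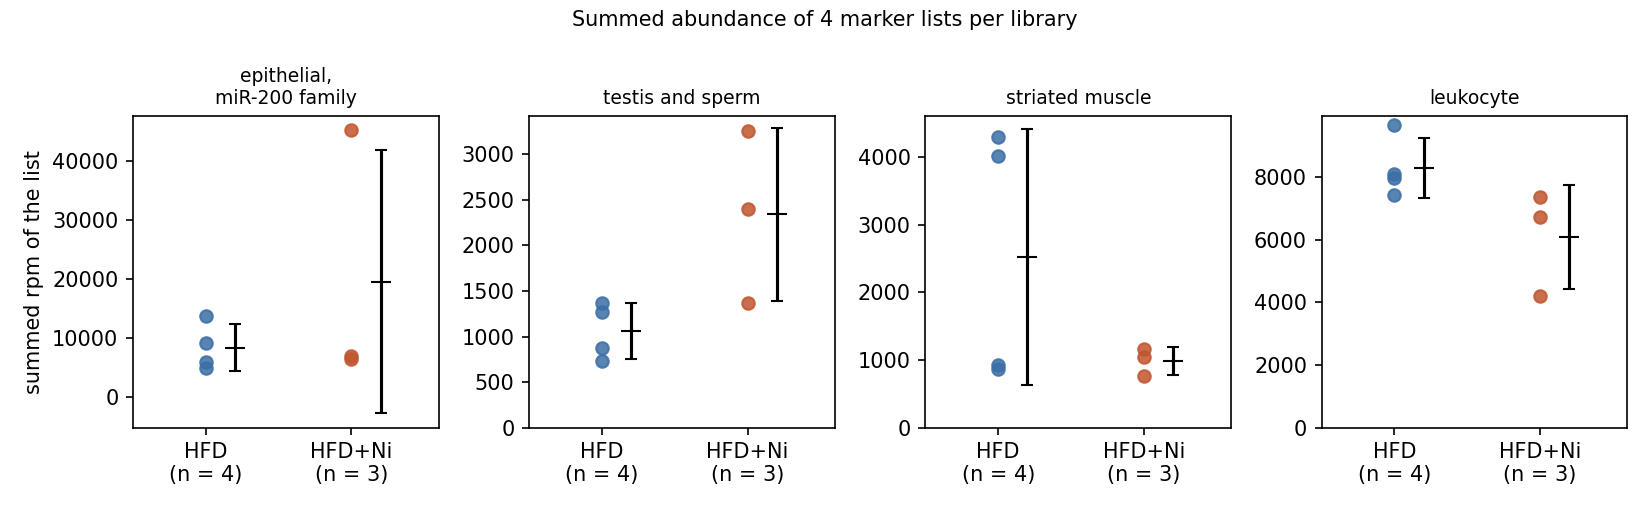
Summed rpm of the epithelial, testis and sperm, striated muscle and leukocyte lists in each library, with points for the libraries (HFD, n = 4; HFD+Ni, n = 3) and black bars for the mean and SD. 1 HFD+Ni library holds 45165 rpm of epithelial miRNAs, and all HFD+Ni libraries lie below the HFD libraries in leukocyte miRNAs.

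Fat cell programmes showed no difference that passed the test with all reads of the 7 libraries. Of 18 miRNAs that promote adipocyte differentiation 14 lay lower (camera adjusted p = 0.161), and of 13 that oppose it 9 lay lower (adjusted p = 0.591), with medians of -0.24 and -0.19. miR-26a-5p, which promotes it, was at 14074 ± 1863 and 12343 ± 3444 rpm, and miR-27b-3p, which opposes it, at 2913 ± 308 and 2585 ± 636 rpm. All 7 miR-30 family members lay lower by a median of -0.26 (adjusted p = 0.157), a list called lower only without HFD+Ni replicate 2 (adjusted p = 0.0310), and 9 of 14 brown and beige adipocyte miRNAs did (adjusted p = 0.440). Among vessel and tissue lists, 6 of 9 endothelial (adjusted p = 0.158) and 8 of 11 hypoxia and angiogenesis miRNAs (adjusted p = 0.158) lay lower, the hypoxia list being called lower only after thinning (adjusted p = 0.0466), and 7 of 9 smooth muscle and mesenchymal miRNAs lay higher (adjusted p = 0.950). For 10 fibrosis miRNAs the median was 0.10 while camera pointed down, a direction that changed with the scaling (adjusted p = 0.925). The erythrocyte list (adjusted p = 0.591), with a median of -1.27 or -0.51 at the bound of its unread member, and the neuronal list (adjusted p = 0.591) were mostly lower. The liver and gut list (adjusted p = 0.950) had a median of 0.04 and a mean of -0.44, and camera pointed down. The imprinted Dlk1-Dio3 list (adjusted p = 0.950) had a median of -0.41, or -0.16 with bounds, and a mean of 0.11, and camera pointed up. In the Sfmbt2 cluster 2 of 3 members lay higher (adjusted p = 0.593). Single libraries decided several of these directions. Without HFD+Ni replicate 1 camera pointed up for the erythrocyte list (adjusted p = 0.329) and the liver and gut list (0.428), and down for the smooth muscle (0.671) and Sfmbt2 (0.602) lists. The direction also turned without HFD+Ni replicate 3 for the neuronal (0.911), fibrosis (0.911) and Dlk1-Dio3 (0.884) lists and the list that opposes adipocyte differentiation (0.911), without HFD replicate 4 for the smooth muscle (0.430), liver and gut (0.699) and Dlk1-Dio3 (0.699) lists, without HFD+Ni replicate 2 for the liver and gut (0.840) and Dlk1-Dio3 (0.745) lists, without HFD replicate 2 for the fibrosis (0.862) list and the list that opposes adipocyte differentiation (0.950), and without HFD replicate 1 for the liver and gut list (0.754).

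**Figure D4:**
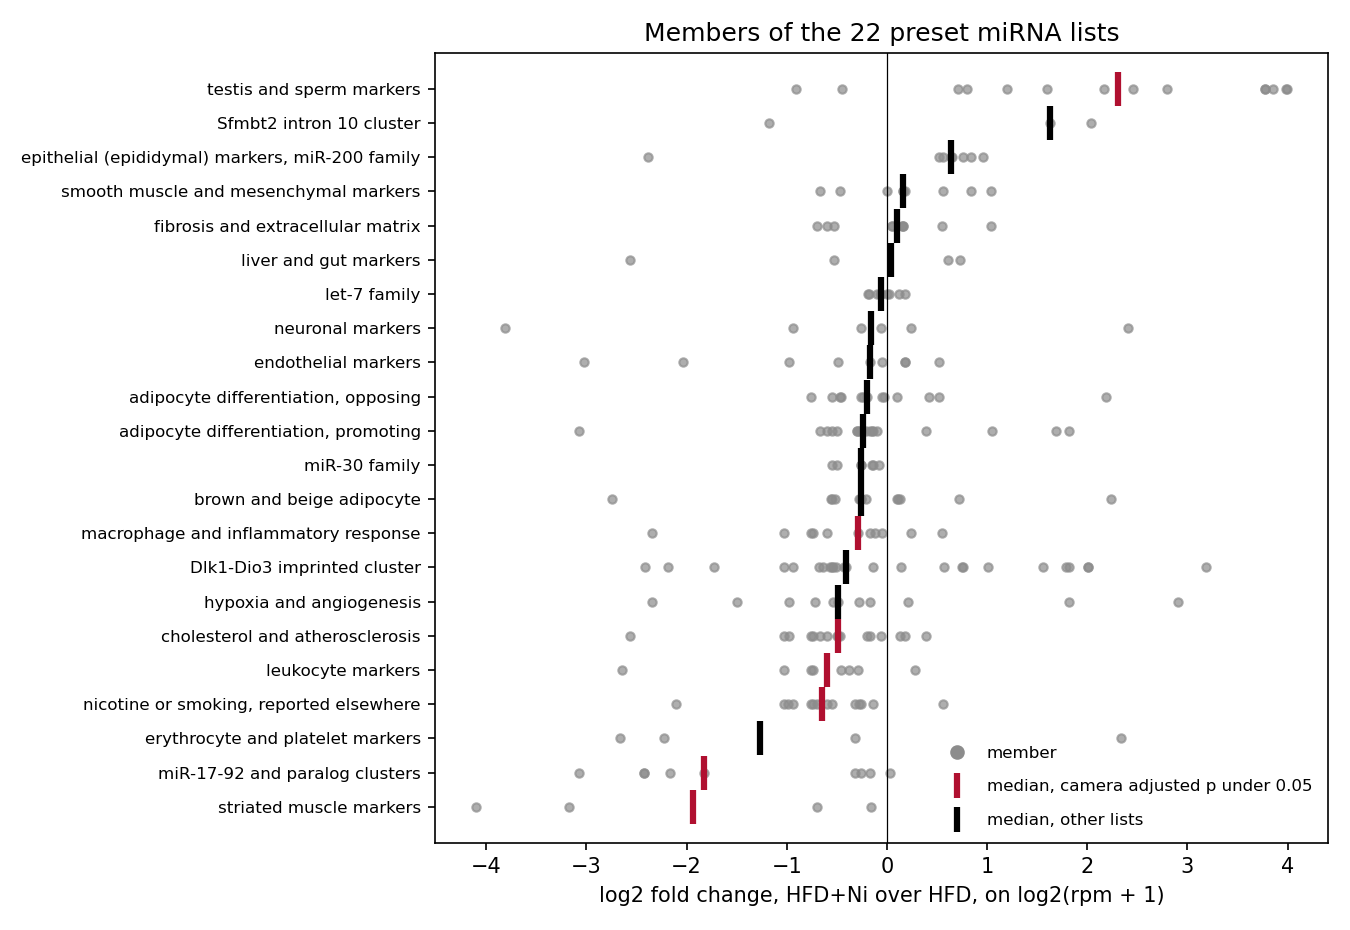
Log2 fold change (HFD+Ni over HFD) of each tested member of the 22 lists, as grey points, with a bar at each list's median, red where the camera adjusted p at the preset correlation is under 0.05. The testis and sperm list has the highest median, 2.31, and the striated muscle list the lowest, -1.94.

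The authors' table of all miRNAs gives 1 miRNA at an FDR under 0.05, miR-1a-3p, with a log2 fold change of -3.44 and an FDR of 0.0254. Their list of 15 changed miRNAs holds 13 higher and 2 lower in HFD+Ni, with the lowest FDR at 0.497, and does not include miR-1a-3p. In the authors' table of all miRNAs all 15 had the listed sign, and 9 were at the authors' unadjusted p under 0.05. In the limma fit 15 of the 15 had the same direction and 3 were at unadjusted p under 0.05, namely miR-204-5p, miR-449a-5p and miR-671-3p, with a lowest adjusted p of 0.830; in edgeR 8 were at unadjusted p under 0.05. The list was chosen on mostly the same libraries and is not independent evidence of direction. The number at unadjusted p under 0.05 was 0 without HFD+Ni replicate 1, 1 without HFD replicate 1 or HFD+Ni replicate 3, and 6 without HFD+Ni replicate 2. Of the 15, 13 had a mean under 100 rpm and 6 had no read in HFD replicates 1, 3 and 4. They include the testis miRNAs miR-449a-5p, miR-465b-5p, miR-465c-5p, miR-470-5p, miR-741-3p and miR-880-3p, the muscle miRNA miR-206-3p, miR-204-3p, miR-190a-5p, miR-30d-3p, miR-338-3p, miR-381-3p and miR-455-5p.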

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

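The tests in this part that weigh explanations were all chosen after the result was seen. Each of 118 values was checked for a library far from the other 3 of the HFD group. The measure was the gap to its nearest neighbour over the whole range. By this 23 stood apart, where a rate of 1 in 20 gives 5.9. That rate is for independent, normally distributed values and does not apply here. A miRNA read in only 1 HFD library is flagged by construction. The let-7 share and the summed let-7 rpm are the same measure, and miR-465b-5p and miR-465c-5p share reads. HFD+Ni, with 3 libraries, was not checked in this way. Of the 23, 15 belong to HFD replicate 2.

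HFD replicate 2 was the highest of its group in reads (1055902) and in miRNAs detected (710). The 10 most abundant miRNAs took 65.0% of its reads and let-7 48.0% (479557 rpm), the lowest values of the group. It was the highest or the only HFD library for miR-455-5p (16.1 rpm), miR-465b-5p and miR-465c-5p (5.68 rpm each, shared reads), miR-470-5p (0.95 rpm), miR-741-3p (12.3 rpm), miR-880-3p (3.79 rpm), miR-7667-5p (1.89 rpm), miR-144-5p (2.84 rpm) and miR-467d-5p (0.95 rpm), all below the level that 1 read gives in HFD replicates 1 and 4 (12.4 and 13.0 rpm) except miR-455-5p. It was the lowest for miR-34b-3p (85.2 rpm). HFD replicate 1 was the highest for miR-125a-5p (24178 rpm), miR-6238 (24.8 rpm) and miR-215-5p (24.8 rpm), the last 2 from 2 reads each. HFD replicate 4 was the highest for miR-126a-3p (30589 rpm), miR-206-3p (753 rpm), liver miR-122-5p (428 rpm) and miR-541-5p (130 rpm), and the lowest for miR-20a-5p (26.0 rpm).

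Epithelial miRNAs in HFD+Ni replicate 1 stood at 6.87 times the median of the other libraries, with miR-205-5p at 11543 rpm and miR-200c-3p at 11431 rpm; all 8 members were also read in other libraries, and miR-200b-3p is in the smoking list too. Counting error is argued against, since the lower 95% Poisson bound of the summed list, 43384 rpm from 2422 reads, lies above the highest other library at 13630 rpm. Of the other 2 HFD+Ni libraries 0 lay above the highest HFD library, and both lay within the range of HFD, which leaves a smaller rise under nicotine undecided. All 6 abundant members, from 3 loci, lay above every other library, by at least 4.41 and up to 8.84 times their median there, which restates the pattern in single miRNAs and does not tell where they came from. One outside source, such as epididymal epithelium taken with the fat, an effect of nicotine and a difference of this sample itself stay open.

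Less muscle in the nicotine samples would lower miR-1a-3p and miR-133a-3p, from the same loci, in step if both came from muscle alone. The log2 ratio of miR-133a-3p to miR-1a-3p was 1.15 ± 0.28 in HFD and 3.63 ± 0.72 in HFD+Ni, a difference of 2.48 with no overlap (exact permutation p = 0.0571, the smallest possible). This argues against less muscle as the whole cause of the low miR-1a-3p only if the pair came from muscle alone, which was not tested. Since miR-1a-3p was picked for its small p, the ratio partly restates that pick. Its HFD+Ni values rest on 2, 13 and 5 reads. Low depth is argued against for miR-1a-3p, since its upper 95% Poisson bound in the pooled HFD+Ni libraries lies under the lower bound of the lowest HFD library. These bounds are 91.6 rpm, from 20 of 337149 reads, and 132 rpm. An effect of nicotine on miR-1a-3p, or on its loading into vesicles, stays open as untested, as does a difference in library preparation between the groups.

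The X-linked testis miRNAs in HFD+Ni replicates 1 and 3 are not explained by low depth in HFD, since the upper bound in the 3 shallower HFD libraries, 47.4 rpm from 6 of 275297 reads, lies far under the lowest lower bound in these libraries, 548 rpm. HFD+Ni replicate 2 held 0 reads (upper bound 21.0 rpm), but that was seen when the pattern was picked, is 1 library and covers counting error only, so it does not decide on a rise under nicotine. The reads of the 7 miRNAs had different profiles in both libraries (permutation p = 0.0001, the smallest that 10000 permutations can give), with 0 reads of miR-470-5p in one and 29 in the other. That p treats reads as independent and covers counting error only, so a few molecules copied by PCR would give it too, and it does not decide whether there was a single testis source. One or several sources of germ cell or epididymal material, and an effect of nicotine, stay open.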

How the results depend on the processing

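Leaving out both the deepest and the shallowest library, thinning, and keeping 1 miRNA per group sharing reads were chosen after seeing the data, as were the counts over splits. The number of miRNAs past adjusted p 0.05 was 0 in edgeR and in limma under every other setting, 1 in DESeq2, and 15 with both libraries left out; those 15 had 0 reads in the HFD libraries used and at most 6 in any. The number at unadjusted p under 0.05 and 2-fold, 9, was 15 with a pseudocount of 10 (11 higher, 4 lower), 16 with no filter (8 and 8), 5 with a filter at 50 rpm (2 and 3), 17 with quantile scaling (10 and 7), 25 in edgeR (17 and 8), 16 in DESeq2 (13 and 3) and 22 with both libraries left out (19 and 3), and ranged from 6 to 24 with single libraries left out. The number of lists called, 7, was 4 with a filter at 50 rpm, 0 with an estimated correlation, 1 with fry and 3 with both libraries left out, and 5 to 8 with single libraries left out. Of the deposited list 14 to 15 kept their direction with single libraries left out, and the number at unadjusted p under 0.05, 3, was 7 with a pseudocount of 10 and 0 to 6 with single libraries left out. Past what these settings change by construction (fewer samples, fewer miRNAs tested), the cause was not tested. An exact permutation test of the deposited list gave no count, since its smallest p is 0.0571.

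Nothing in the labels says that equal replicate numbers pair the libraries. Deviations from the group means correlated at -0.08, 0.07 and -0.19 for the same numbers. For different numbers they ranged from -0.24 to 0.20, so the correlations cannot decide on a pairing. With the number as a replicate block, which also takes HFD replicate 4, alone in its block, out of the comparison, the lists called were 4 (1 higher, 3 lower; 6 without HFD replicate 4 and no block), the deposited list had 1 member at unadjusted p under 0.05 and 14 with the listed direction, and the other counts were 0 and 9.

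For 92 named miRNAs, 1673 of 1909 values under alternatives stayed on their side of the threshold, 84 no longer reached unadjusted p under 0.05, 73 newly did, 79 moved without a test and 0 reversed. None of the 11 at unadjusted p under 0.05 changed sign in any setting, and 44 of the other 81 did in at least 1. miR-1a-3p and miR-223-3p kept unadjusted p under 0.05 with each of the 7 libraries left out. Of 31 alternative values of library composition none moved by more than 1 SD, and 4 changed sign.

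The libraries can be split into 4 and 3 in 35 ways. For miRNAs past adjusted p the real count is 0, which all 35 splits reach by construction, so the splits say nothing about it; the highest other was 2. At unadjusted p and 2-fold 28 splits gave at least 9, so chance cannot be excluded. The highest other there was 27, or 3 times the real count, for HFD replicates 1 and 4 with HFD+Ni replicate 1 against the rest. These are the 3 shallowest libraries. Whether depth or another structure of the samples gives that count was not tested. For the lists, 1 split, the real one, gave 7 by camera at the preset correlation and the highest other was 6. That does not exclude chance either. Several counts were taken over the same 35 splits after seeing the data, and no correction was made for this. The lists also share members, and 0 are called with an estimated correlation. Of the 15 miRNAs in the deposited list 13 have a mean under 100 rpm, while 1 read is 18.6 rpm in the smallest library. In the simulated data 23.2% of 2-fold and 44.4% of 4-fold changes were recovered at a mean of 500 rpm or more. The simulation gave all miRNAs the same dispersion, 0.416, whatever their abundance. It therefore cannot tell how far abundance limits the calls in the real data.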

Other observations

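The tests in this part were chosen after the result was seen. Several tissue markers varied between libraries without following nicotine. Liver miR-122-5p was at 428 rpm in HFD replicate 4 and 725 rpm in HFD+Ni replicate 3, and at 0 to 26.5 rpm in the other 5 libraries. miR-9-5p, a miRNA of neurons, was at 5277 rpm in HFD+Ni replicate 1, 2388 rpm in HFD replicate 1, and 46.5 rpm in HFD+Ni replicate 3. The erythrocyte miRNA miR-486b-5p ranged from 0 in HFD+Ni replicate 1 to 1159 rpm in HFD replicate 2. In HFD+Ni replicate 1, 90 of the 387 tested miRNAs had their highest value and 143 had no read.

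Testis and sperm miRNAs made up 6 of the 15 miRNAs in the deposited list, where a random draw from the 387 tested would hold 0.543 (one-sided Fisher's exact p = 2.84e-06; 6.25e-05 after Benjamini-Hochberg adjustment over 22 lists). Fisher's test takes miRNAs as independent draws, whereas the X-linked members of the 6 came mainly from HFD+Ni replicates 1 and 3. Its p therefore overstates the evidence. Of the 6, miR-465b-5p and miR-465c-5p share their reads, and the list was chosen on mostly the same libraries, so the overlap is not independent of the difference in these samples. Whether the additional column of the list, which matches no label, carries them was not analysed here.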
